A study of Leucoraja erinaceus with 6 samples.

How the data were processed

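RNA was measured in 6 libraries of manually sorted cells from the spinal cord of little skate (Leucoraja erinaceus) embryos at stages 30 to 31. There were 3 libraries of pectoral fin motor neurons (replicates 1, 2 and 3) and 3 libraries of tail spinal cord cells (replicates 1, 2 and 4), grouped by the source given in the labels. Total RNA was extracted with a kit for very small samples (Arcturus PicoPure) and made into Illumina TruSeq stranded mRNA libraries, per the labels' protocols. The labels do not say whether the libraries came from separate embryos, so p-values measure only the spread between these libraries, which may be technical.

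The authors deposited 1 table of TPM, a transcript abundance scaled for length and library total, with a column for each library, per the file headers. The submitters' processing notes name Trimmomatic 0.33, Salmon 0.8.2 and edgeR 3.18.1, without saying which step each served. Each row of the table pairs a contig of a Trinity assembly, a transcriptome built from reads without a genome, with 1 protein accession, and 1576 of the 7080 rows also carry a protein description. The genome build, the assembly's source reads and the protein search are not given in the sources used here. The deposited table also gives a sum, a log fold change and a p-value for each row. The authors' deposited p-values lay within 1e-04, in all 7080 rows, of a two-sided equal-variance comparison of the TPM values recomputed here. The sum and the fold change columns were not used here.

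The table had 7081 rows, and 1 exact repeat, the row of ALDH1A2, was removed. Gene names were taken only from the descriptions, which were matched by hand to standard symbols. The few values at the head of the table had been seen by then. Zebrafish-style suffixes such as the letter in homeobox B7a were dropped, so a symbol names a described protein match and not a verified skate ortholog. None of the table's accessions matched the skate reference gene table (0 matches), and no genome coordinates were used. Rows without a description are named by their contig.

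Depth per library is unknown, because TPM keep no read number, so no counting interval or detection limit could be given. The deposited rows held 48449 to 74224 TPM. If the values were scaled to the whole library, this is 4.84% to 7.42% of its total. In pectoral replicate 1 the rows summed to 50000 TPM. The sources used here do not say whether values were rescaled after rows were chosen. An exact 0 was treated as listed at 0 and not as absence, since rows of genes that every cell uses were also listed at 0. In tail replicate 4, 5 of 19 oxidative phosphorylation rows and 2 of 65 ribosomal protein rows were at 0. For rows with a 0 in any library, library values are given in place of a mean.

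The main test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend) on log2(TPM + 1), two-sided, over the 3752 rows with at least 1 TPM in at least 3 of the 6 libraries. Calls were rows with a Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences of mean log2(TPM + 1), pectoral minus tail, and the pseudocount of 1 makes them smaller than the ratio of TPM for low rows. The comparison, the alternatives, the 25 gene lists and the naming rule were fixed before the data were examined. In a list, a symbol with several rows was represented by its row of highest mean TPM. Lists with at least 3 tested members (11 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over those lists, and again with an estimated correlation and with fry. The smaller lists have counts only.

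The naming rule took up to 12 described rows in each direction past the threshold, with separated groups and a mean of at least 10 TPM in the higher group, of which there were 0. From each list it took up to 4 members past the threshold (0 were) and up to 2 other tested members of highest mean TPM. It always took 12 motor neuron and limb column genes (MNX1, ISL1, ISL2, LHX3, CHAT, SLC18A3, SLC5A7, FOXP1, ALDH1A2, LHX1, ETV4 and RET), all Hox genes and, in the closing section, the genes ranked highest in the authors' table. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen, and this is said where they appear. Motor neuron identity was checked with ISL1, ISL2, CHAT and SLC18A3 by an exact two-sided permutation test of 3 libraries against 3, whose smallest possible p is 0.1.

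The scripts were tested on simulated libraries with the real row means and the row variances after empirical Bayes shrinkage. Rows were drawn independently, and 200 of 3752 were changed. Of rows changed by 2 log2 units 0% were called, by 4 units 62% and by 6 units 99.5%. Simulated values below 0 TPM were set to 0, which cut the folds. The median fold estimated in tested changed rows was 1.73, 3.29 and 4.57. Changed rows that failed the filter count as not called. Unchanged rows called numbered 0, 2 and 6.

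Alternatives covered the pseudocount (0.1, 0.5 and 5), no filter and a filter of 5 TPM, median-ratio and quantile scaling, the variance model, array weights, each library left out, the replicate number as a block, rows of 1 gene name summed, an adjusted p of 0.01 and a minimum fold of 2. Fits without a library used the rows chosen over all 6 libraries. Added after seeing the data were the authors' deposited p-values adjusted over the table, the fit without pectoral replicate 1 and tail replicate 4 together, fits without a library with the filter repeated on the other 5, and rows of 1 Trinity gene summed.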

Results

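The series set out to screen the transcriptome for markers of pectoral fin motor neurons, the spinal neurons that drive the large paired fins of the skate. Expression was compared between 3 libraries of pectoral fin motor neurons and 3 libraries of tail spinal cord cells. By their labels the groups differ both in cell class and in axial level. A difference between them can therefore not be assigned to either of these alone. Values are TPM from the authors' deposited table, and read depth per library is unknown. The largest row in all 6 libraries was a row described as zgc:158463, named after its values were seen, at 12521 to 29726 TPM. Tail replicate 4 had 3552 of 7080 rows listed at 0 and 1934 rows at 1 TPM or more. Pectoral replicate 1 had 5 rows at 0 and 5364 rows at 1 TPM or more. Across tested rows, log2 values of 2 libraries of 1 group correlated with r of 0.36 to 0.48, and those of libraries from different groups with r of 0.27 to 0.44. These are correlations across rows, which are not independent replicates.

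Motor neuron genes were examined first, because they check the labels. ISL1, a LIM homeodomain factor of motor neurons, stood at 1.63, 1.22 and 4.81 TPM in pectoral replicates 1, 2 and 3. In tail replicates 1, 2 and 4 it stood at 0.249, 0.0563 and 0 TPM. Its relative ISL2 stood at 3.43, 0.956 and 0.328 TPM in the pectoral libraries and at 0.139, 0 and 0 TPM in the tail libraries. Both genes had every pectoral library above every tail library, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. CHAT, which makes acetylcholine, showed no such separation, with 2.61, 3.72 and 0 TPM against 2.85, 2.81 and 0.522 TPM (exact permutation p = 0.8). SLC18A3, the vesicular acetylcholine transporter, averaged 3.19 ± 0.965 TPM in pectoral and 1.85 ± 1.56 TPM in tail libraries (SD, n = 3 each, exact permutation p = 0.3). No described row named MNX1, LHX3 or SLC5A7, and these genes were not analysed here.

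**Figure D1:**
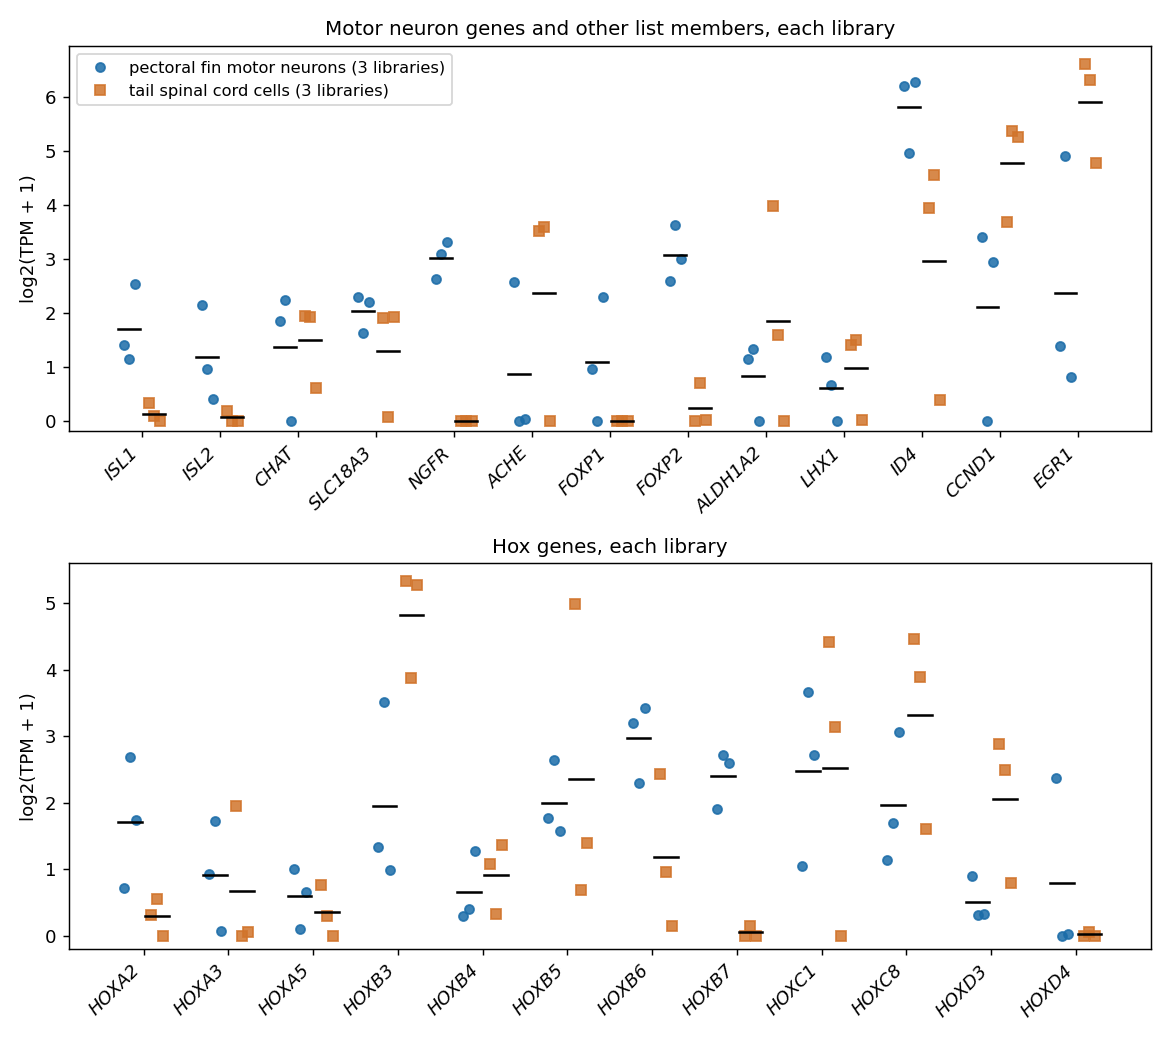
Expression in each of the 6 libraries, as log2(TPM + 1), of motor neuron genes and other list members (top) and of Hox genes (bottom). Points are libraries, 3 per group, and black bars are group means. The 3 pectoral libraries lie above the 3 tail libraries for ISL1, ISL2, NGFR, FOXP2, ID4, HOXA2 and HOXB7, and below them for CCND1 and HOXB3.

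NGFR, the low-affinity neurotrophin receptor, stood at 5.16, 7.58 and 8.96 TPM in the pectoral libraries and was listed at 0 in all 3 tail libraries. Its limma adjusted p was 0.49 over all rows tested. NGFR was 1 of 5 tested motor neuron and cholinergic genes, of which 0 passed over all rows and 1, NGFR, passed when adjusted over the list alone (adjusted p = 0.021). That call held in 5 of the 6 fits without a library and was lost without tail replicate 2 (adjusted p = 0.066) and with a pseudocount of 5 (adjusted p = 0.072). NGFR reached 1 TPM in the pectoral libraries only, so the fits without 1 pectoral library rested on rows chosen over all 6. With the filter repeated, NGFR would not have been tested in those fits. ACHE, acetylcholinesterase, stood at 4.93, 0 and 0.0258 TPM in pectoral and 10.5, 11.01 and 0 TPM in tail libraries. The list had a median log2 fold change of 0.75, which was 0.13 without tail replicate 2, 1.59 with a pseudocount of 0.1 and 0.28 with one of 5. For the list camera gave an adjusted p of 0.17, or 0.82 with an estimated correlation.

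In the comparison of all rows, 2 rows were higher in pectoral fin motor neurons and 1 row was higher in tail spinal cord cells. None of the 3 carried a description, and they were chosen for naming after their values were seen. TRINITY_DN18143_c9_g1_i1 stood at 48.6, 94.5 and 95.2 TPM in pectoral libraries and at 0.152, 0 and 0 TPM in tail libraries, a log2 fold change of 6.20 (SE 0.91, limma adjusted p = 4.478e-04). TRINITY_DN18690_c1_g8_i1 stood at 40.7, 47.5 and 58.5 TPM against 2.89, 0 and 2.53 TPM, a log2 fold change of 4.37 (SE 0.91, limma adjusted p = 0.0486). TRINITY_DN18166_c8_g3_i1 stood at 2.67, 2.49 and 0 TPM in pectoral and 44.1, 37.04 and 244 TPM in tail libraries, a log2 fold change of -5.00 (SE 0.94, limma adjusted p = 0.0152).

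Among the 3752 tested rows, 264 had an unadjusted p under 0.05, of which 116 were higher in pectoral and 148 in tail libraries, where chance gives 187.6. The 3 libraries of one group lay above all 3 of the other in 442 rows, or 11.8%, where chance gives 10%. Of these, 157 were higher in pectoral and 285 in tail libraries, where chance gives 187.6 each way. In the authors' deposited table, 219 of 7080 p-values were under 0.05, where evenly spread p-values give 354, and 0 passed after adjustment over the table. That expectation need not hold for an equal-variance test on TPM in which many values are 0. Median-ratio scaling left 1 row higher in pectoral and 0 in tail, and quantile scaling 3 and 0. Median-ratio scaling moved the median log2 fold change of all tested rows from -0.18 to 0.08, a shift of 0.26. That median was 0.17 without tail replicate 1 and -0.44 without tail replicate 4, with 55.04% and 33.8% of rows positive against 43.5% with all 6 libraries. The first of the 3 rows passed in every fit without 1 library that kept the rows chosen over all 6. With the filter repeated on the other 5 libraries it was not tested without any 1 pectoral library, since it reached 1 TPM in the pectoral libraries only. With the rows kept, the second was lost without pectoral replicate 1, 2 or 3 or tail replicate 1 or 2, and the third without pectoral replicate 1 or 3 or tail replicate 1 or 4. With the filter repeated, the second was lost without the same libraries and the third only without tail replicate 1 or 4. Without pectoral replicate 1 and tail replicate 4 together, 0 rows passed and 368 had an unadjusted p under 0.05. With array weights, which ran from 0.41 for tail replicate 4 to 2.28 for tail replicate 2, 11 rows passed higher in pectoral and 15 in tail libraries. Of these 26 rows 6 carried a description, and EGR1 was the 1 among them on a list. In simulated data, 0% of rows changed by 2 log2 units were called and 62% of those changed by 4. The simulation used shrunken variances and set low values to 0, so these shares need not hold for the real rows.

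Hox genes give neurons their position along the body axis. Of the paralog groups 1 to 8, 11 list genes had a row and 6 were tested, and 0 passed over all rows. HOXB7 stood at 2.75, 5.56 and 5.05 TPM in pectoral libraries and at 0, 0.109 and 0 TPM in tail libraries (log2 fold change 2.36, SE 0.87, limma adjusted p = 0.54). HOXB3 averaged 4.31 ± 5.31 TPM in pectoral and 30.2 ± 14.3 TPM in tail libraries (log2 fold change -2.88, SE 0.95, limma adjusted p = 0.49). Both had separated groups, and both passed when adjusted over the list alone (adjusted p = 0.032 and 0.028). Each call held in 2 of the 6 fits without a library. HOXB7 reached 1 TPM in the pectoral libraries only, so its 2 fits, without pectoral replicate 2 or 3, rested on rows chosen over all 6. With the filter repeated, HOXB7 would not have been tested in them. The HOXB7 call was lost without pectoral replicate 1 or any 1 tail library (highest adjusted p 0.12), and that of HOXB3 without pectoral replicate 1 or 3 or tail replicate 1 or 4 (highest adjusted p 0.082). Both were also lost with no filter and without pectoral replicate 1 and tail replicate 4 together, and that of HOXB7 with a pseudocount of 5 (highest adjusted p 0.13 for HOXB7 and 0.21 for HOXB3). HOXB6 averaged 7.27 ± 3.002 TPM against 1.81 ± 2.27 TPM, with overlapping groups. The row described as homeobox C8a (HOXC8) averaged 3.59 ± 3.27 TPM against 12.3 ± 9.61 TPM, also with overlapping groups. HOXB5, at 3.21 ± 1.77 TPM against 11.02 ± 17.1 TPM, and HOXB4, at 0.655 ± 0.659 TPM against 0.976 ± 0.671 TPM, overlapped too. A row described as homeo box C1a (HOXC1), outside the list, stood at 1.06, 11.7 and 5.56 TPM in pectoral and 20.4, 7.77 and 0 TPM in tail libraries. Whether the skate has these HoxC genes was not checked here, and the descriptions alone do not show it.

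Among the Hox rows that were too low to test, HOXA2 stood at 0.641, 5.47 and 2.33 TPM in pectoral libraries and 0.242, 0.471 and 0 TPM in tail libraries. HOXD3 averaged 0.453 ± 0.356 TPM in pectoral and 3.91 ± 2.90 TPM in tail libraries. HOXA3 stood at 0.908, 2.29 and 0.0484 TPM against 2.88, 0 and 0.0377 TPM. HOXA5 stood at 1.01, 0.0739 and 0.580 TPM against 0.690, 0.225 and 0 TPM, and HOXD4 at 4.15, 0 and 0.0166 TPM against 0, 0.0359 and 0 TPM. The HOXA3 and HOXD4 rows and the tested HOXB4 row are contigs of 1 Trinity gene. Their names and values may therefore not mark separate genes, and the count of 11 list genes with a row may be too high. The list's median log2 fold change was -0.31 and its mean -0.12. The median was -0.08 with median-ratio scaling, 0.38 without tail replicate 1 and -0.81 without tail replicate 2, while camera ranked it upward against other rows (adjusted p = 0.89, or 0.92 with an estimated correlation). The list ranked downward with quantile scaling, a pseudocount of 5, without pectoral replicate 3 and without tail replicate 2, and fry gave a downward balance. No described row named a gene of paralog groups 9 to 13, which mark the caudal body axis.

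Of 27 listed genes of limb-innervating motor columns 7 had a row, against 175 of 741 genes over all lists. FOXP1, which specifies the lateral motor column, had 1 described row, which was too low to test. That row stood at 0.940, 0 and 3.90 TPM in pectoral libraries and was listed at 0 in all 3 tail libraries. Undescribed rows of its Trinity gene are given in the closing section. ALDH1A2, a retinoic acid synthesis enzyme, stood at 1.20, 1.51 and 0 TPM in pectoral and 14.9, 2.004 and 0 TPM in tail libraries. LHX1 stood at 1.26, 0.587 and 0 TPM against 1.65, 1.82 and 0.00990 TPM. Of the 7 limb column genes with a row, 2 were tested and 0 passed, also when adjusted over the list alone. No described row named ETV4 or RET. Of the retinoic acid genes, 2 were tested and 0 passed by either adjustment, and RARG, a retinoic acid receptor, stood at 3.33, 0 and 0.133 TPM against 35.4, 0.147 and 9.18 TPM.

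Among spinal interneuron transcription factors, 0 of 4 tested genes passed over all rows. FOXP2, a forkhead factor of ventral interneurons, was the member that passed when adjusted over the list alone (adjusted p = 0.032), and is named after its values were seen. It stood at 4.99, 11.3 and 6.96 TPM in pectoral libraries and 0, 0.617 and 0.0119 TPM in tail libraries (log2 fold change 2.83, SE 1.001, limma adjusted p = 0.54). The FOXP2 call held in 2 of the 6 fits without a library, and was lost without any 1 pectoral library or tail replicate 1, without pectoral replicate 1 and tail replicate 4 together and with a pseudocount of 5 (highest adjusted p 0.085). LHX5 averaged 4.35 ± 5.67 TPM in pectoral and 11.1 ± 10.3 TPM in tail libraries. The list's median log2 fold change was 1.24 (camera adjusted p = 0.17, or 0.82 with an estimated correlation). The median was 1.96 without tail replicate 1, 0.86 without tail replicate 4 and 0.78 with the replicate block. With a pseudocount of 0.1 it was 2.16, and with one of 5 it was 0.55.

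Genes of inhibitory transmission had a median log2 fold change of -0.93 over 4 tested members, and 0 passed by either adjustment (camera adjusted p = 0.35, or 0.82 with an estimated correlation). In fits without 1 library the median ranged from -1.63 without tail replicate 4 to -0.38 without tail replicate 1. It was -1.79 without pectoral replicate 1 and tail replicate 4 together. SLC6A5, the neuronal glycine transporter, stood at 1.70, 0 and 0 TPM in pectoral and 10.05, 5.78 and 0 TPM in tail libraries. SLC17A6, a vesicular glutamate transporter and the 1 excitatory gene tested, stood at 1.28, 31.5 and 0 TPM against 6.14, 0 and 0 TPM and did not pass by either adjustment. Pan-neuronal maturation genes had a median of 0.64 over 5 tested members, with 0 past the threshold by either adjustment (camera adjusted p = 0.38, or 0.82 with an estimated correlation). The median was 0.10 without tail replicate 4, 0.99 without tail replicate 1 and -0.03 without pectoral replicate 1 and tail replicate 4 together. With a pseudocount of 0.1 it was 1.17, and with one of 5 it was 0.22. Their member GAP43, a growth cone protein, averaged 27.9 ± 13.96 TPM in pectoral and 18.3 ± 21.4 TPM in tail libraries, and RAB3A, of synaptic vesicles, stood at 1.98, 3.40 and 0 TPM against 7.41, 3.98 and 0.286 TPM. Of axon guidance genes, 2 were tested and 0 passed by either adjustment, with EFNB1 at 2.04 ± 2.67 TPM against 11.1 ± 4.99 TPM and NCAM1 at 7.23 ± 5.48 TPM against 15.2 ± 16.01 TPM. The 4 voltage-gated ion channel genes with a row were too low to test.

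Markers of progenitors and dividing cells went both ways. ID4, an inhibitor of bHLH factors found in progenitors and glia, averaged 59.9 ± 25.8 TPM in pectoral and 12.4 ± 11.2 TPM in tail libraries (log2 fold change 2.86, SE 0.94, limma adjusted p = 0.49). FABP7, a radial glial lipid carrier, averaged 29.5 ± 17.3 TPM against 11.6 ± 8.19 TPM. The other 3 tested progenitor genes, SOX2, SOX9 and PAX6, are named after their values were seen. They had negative log2 fold changes (-1.41, -1.68 and -0.64) and overlapping groups. Of 5 tested progenitor genes 0 passed over all rows, and ID4 passed when adjusted over the list alone (adjusted p = 0.024), in 3 of the 6 fits without a library (lost without pectoral replicate 1 or 3 or tail replicate 4, highest adjusted p 0.15). The ID4 call was also lost with a pseudocount of 0.1, with no variance trend and without pectoral replicate 1 and tail replicate 4 together. The progenitor list had a median of -0.64 (-0.33 without pectoral replicate 3) and a mean of 0.07, and camera ranked it upward (adjusted p = 0.73, or 0.85 with an estimated correlation). It ranked downward without pectoral replicate 1 and tail replicate 4 together, and fry gave a downward balance. CCND1, which drives entry into the cell cycle, stood at 9.59, 0 and 6.66 TPM in pectoral and 11.9, 40.3 and 37.2 TPM in tail libraries. MCM7, of the replicative helicase and named after its values were seen, stood at 1.32, 1.62 and 1.07 TPM in pectoral libraries and was listed at 0 in all 3 tail libraries. Of 3 tested cell cycle genes 0 passed over all rows, while CCND1 and MCM7 passed in opposite directions when adjusted over the list alone (adjusted p = 0.029 each). The CCND1 call was lost without pectoral replicate 2 or tail replicate 2 or 4 (highest adjusted p 0.19), and the MCM7 call held in 1 of the 6 such fits, that without pectoral replicate 3 (highest adjusted p 0.18). Both calls were also lost with a pseudocount of 0.1, no filter, quantile scaling and without pectoral replicate 1 and tail replicate 4 together, and that of MCM7 with no variance trend and with robust empirical Bayes (highest adjusted p 0.29). MCM7 reached 1 TPM in the pectoral libraries only, so its fit without pectoral replicate 3 rested on rows chosen over all 6. With the filter repeated, MCM7 would not have been tested in that fit. CDK1 averaged 1.24 ± 0.116 TPM against 1.29 ± 1.396 TPM, and the list had a median of 0.12 and a mean of -0.44. The median was 0.00 with quantile scaling, -0.13 and -0.09 without tail replicates 1 and 2 and 0.59 without tail replicate 4, with camera upward (adjusted p = 0.89, or 0.91 with an estimated correlation). The list ranked downward with no filter, without pectoral replicate 1, without tail replicate 1 or 2, and fry gave a downward balance.

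**Figure D2:**
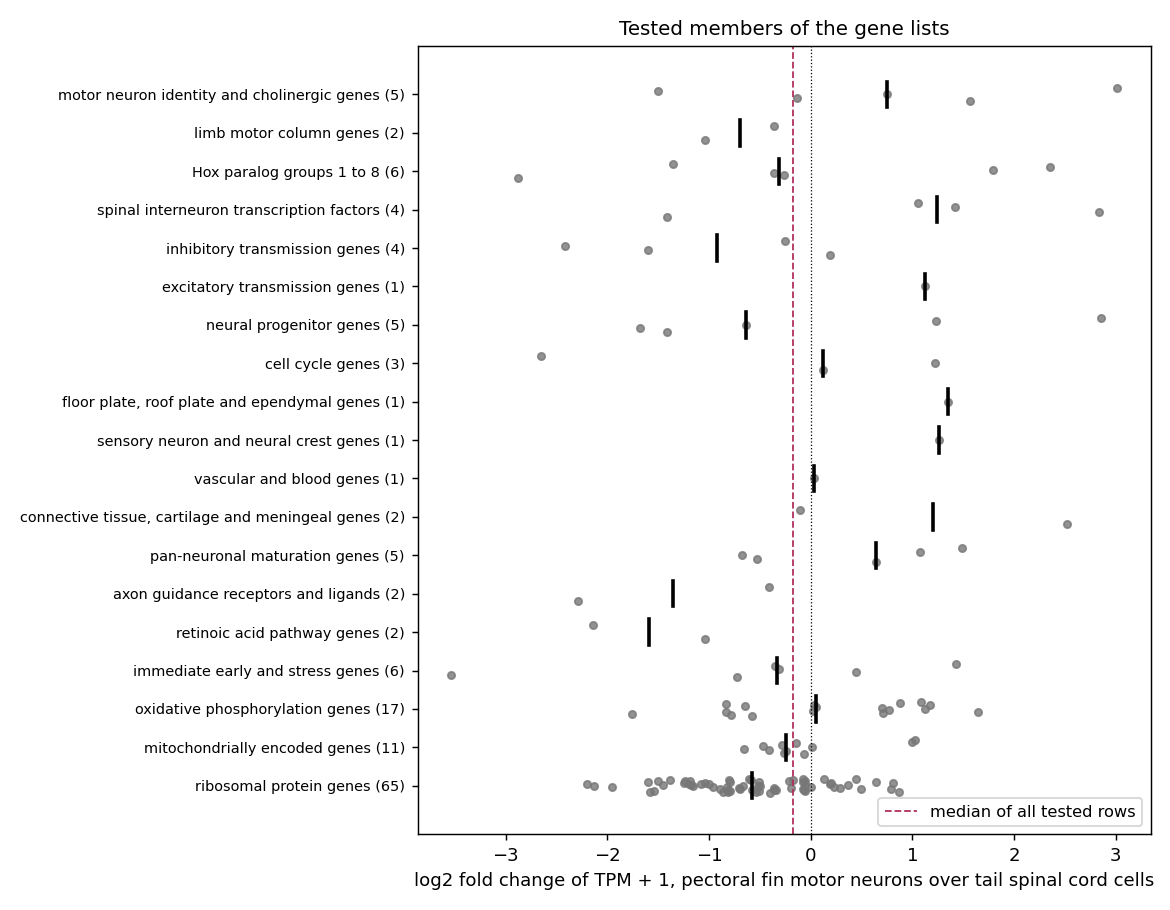
Log2 fold changes of TPM + 1, pectoral fin motor neurons over tail spinal cord cells, of the tested members of 19 gene lists, with the number tested in brackets. Points are genes, black bars are list medians, and the dashed line is the median of all tested rows (-0.18). Ribosomal protein genes lie mostly below 0, with 52 of 65 negative as deposited and 41 and 38 of 65 under median-ratio and quantile scaling.

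Few markers of other cell types had a row, but over all lists only 175 of 741 genes had one. A marker without a row therefore does not show that a cell type was absent. Of the floor and roof plate list, NTN1, an axon attractant, was the 1 gene tested, at 4.21 ± 3.94 TPM in pectoral and 0.970 ± 1.34 TPM in tail libraries, and did not pass by either adjustment. TAC1, a sensory neuropeptide precursor, stood at 1.24, 1.49 and 1.69 TPM in pectoral and 0.0900, 0 and 0 TPM in tail libraries (log2 fold change 1.26, SE 0.53, limma adjusted p = 0.60). As the 1 tested gene of the sensory neuron list, TAC1 passed when adjusted over the list alone, where no correction applies (adjusted p = 0.023 by limma). That call was lost without any 1 tail library, with no filter, with no variance trend and without pectoral replicate 1 and tail replicate 4 together (highest adjusted p 0.14). TAC1 reached 1 TPM in the pectoral libraries only, so the fits without 1 pectoral library, which kept the call, rested on rows chosen over all 6. With the filter repeated, TAC1 would not have been tested in those fits. COL2A1, the cartilage collagen, stood at 2.22, 69.0 and 4.49 TPM in pectoral and 4.91, 0.109 and 0 TPM in tail libraries, and SPARC at 1.14, 0.832 and 11.96 TPM against 6.03, 8.09 and 0 TPM. These were the 2 tested connective tissue genes, and 0 passed by either adjustment. TAGLN, of smooth muscle, averaged 31.0 ± 22.6 TPM in pectoral and 29.4 ± 19.6 TPM in tail libraries and was the 1 tested vascular gene, which did not pass by either adjustment. The glial list (1 gene with a row) and the tail bud list (3 genes with a row) held no tested gene. No described row named a gene of the skeletal muscle or microglia lists.

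EGR1, an immediate early transcription factor induced by activity or handling, averaged 10.5 ± 16.2 TPM in pectoral and 67.5 ± 36.8 TPM in tail libraries (log2 fold change -3.54, SE 0.97, limma adjusted p = 0.31). It passed when adjusted over the list alone (adjusted p = 0.0055), although pectoral replicate 2, at 29.2 TPM, lay above tail replicate 4, at 26.5 TPM. That call held in 4 of the 6 fits without a library and was lost without pectoral replicate 1 or tail replicate 1 (highest adjusted p 0.069). It was also lost without pectoral replicate 1 and tail replicate 4 together (adjusted p = 0.15). HSPA8, a constitutive chaperone, averaged 36.6 ± 17.4 TPM against 44.1 ± 13.8 TPM. Of 6 tested immediate early and stress genes 0 passed over all rows, while EGR1 passed over all rows without pectoral replicate 2 (log2 fold change -4.81, limma adjusted p = 0.014) and with array weights (-4.12, limma adjusted p = 0.0040). Their median was -0.34 as deposited and -0.14 without tail replicate 1, but 0.01 with median-ratio and 0.15 with quantile scaling (camera adjusted p = 0.65, or 0.85 with an estimated correlation).

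Ribosomal protein genes had a median log2 fold change of -0.58 over 65 tested members, or -0.40 relative to all tested rows, and 52 of 65 were negative. With median-ratio scaling the median was -0.26 with 41 negative, and with quantile scaling -0.08 with 38 negative. Without tail replicate 1 it was -0.33. No member passed by either adjustment, while 5 had an unadjusted p under 0.05, all higher in tail libraries. The camera adjusted p was 0.061, or 0.82 with an estimated correlation. It was 0.46, 0.018 and 0.0039 without pectoral replicates 1, 2 and 3, and 0.17, 0.012 and 0.14 without tail replicates 1, 2 and 4. With median-ratio scaling it was 0.20 and with quantile scaling 0.54. RPL10A averaged 41.8 ± 22.3 TPM in pectoral and 121 ± 59.5 TPM in tail libraries. Oxidative phosphorylation genes had a median of 0.05 over 17 tested members as deposited, 0.35 with median-ratio scaling and 0.59 with quantile scaling. Without 1 library it ranged from -0.03 without tail replicate 4 to 0.59 without pectoral replicate 1, with 0 members of the list past the threshold by either adjustment (camera adjusted p = 0.52, or 0.82 with an estimated correlation). Their most abundant members, ATP5B and NDUFA4, stood at 16.1 ± 12.9 against 13.5 ± 5.93 TPM and 12.4 ± 10.8 against 16.1 ± 6.49 TPM. Mitochondrially encoded genes had a median of -0.24 over 11 members as deposited, 0.11 with median-ratio scaling and 0.00 with quantile scaling. It was -0.13 without pectoral replicate 3 and -0.38 without tail replicate 1, with 0 members past the threshold by either adjustment (camera adjusted p = 0.73, or 0.91 with an estimated correlation). Camera ranked the list downward as deposited, and upward with either scaling, without pectoral replicate 3 and without tail replicate 2. MT-ND2 averaged 4878 ± 1138 TPM in pectoral and 5801 ± 903 TPM in tail libraries, and MT-CO3 averaged 1270.0 ± 22.96 TPM and 1671 ± 974 TPM.

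The list tests at the preset correlation gave 0 of 11 lists past an adjusted p of 0.05, and neither the estimated correlation nor fry, which asks whether a list's genes move on balance one way, gave any (smallest adjusted p 0.82 and 0.51). The table itself limits what can be found on the tail side. No row (0 of 7080) was listed at 0 in all 3 pectoral libraries, whereas 487 rows were listed at 0 in all 3 tail libraries.

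**Figure D3:**
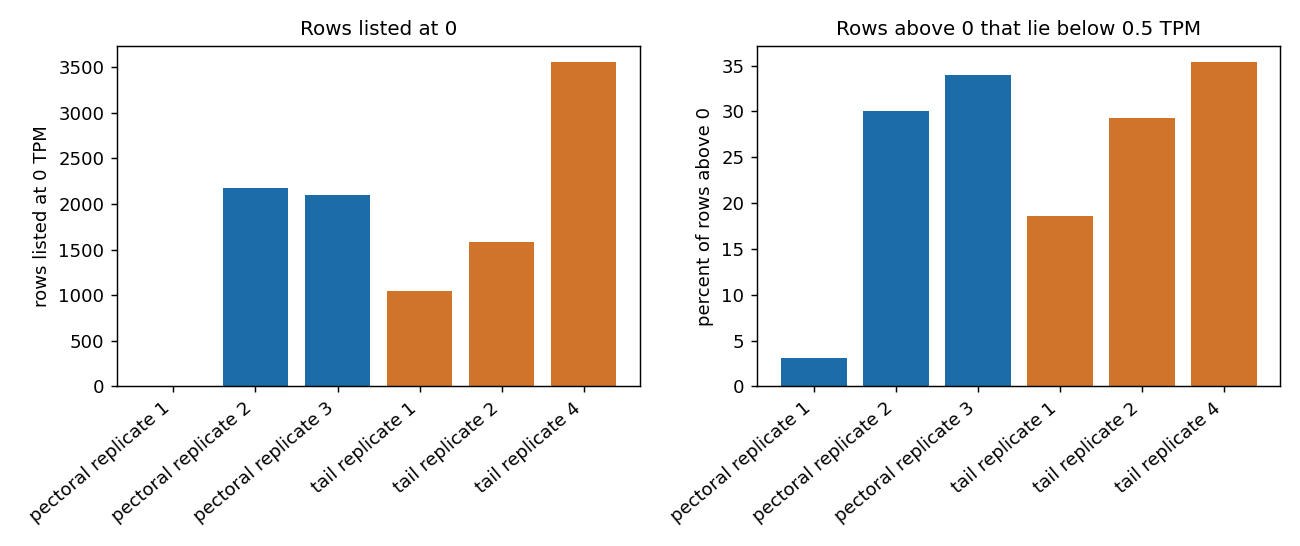
Rows listed at 0 TPM in each library (left) and the percent of rows above 0 that lie below 0.5 TPM (right), for 3 pectoral (blue) and 3 tail (orange) libraries over 7080 rows. Pectoral replicate 1 has 5 rows at 0 and 3.11% of its rows above 0 lie below 0.5 TPM, against 18.6% to 35.4% in the other 5 libraries.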

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

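The deposited p-values, the fit without 2 libraries, the repeated filter and the sums over Trinity genes were added after the data were seen. Against 2 rows higher in pectoral and 1 higher in tail libraries, the counts were 1 and 0 with a pseudocount of 0.1, 1 and 1 with 0.5 and with 5, 2 and 1 with no filter, and 1 and 0 with a filter of 5 TPM. They were 1 and 0 with median-ratio scaling, 3 and 0 with quantile scaling, 1 and 0 with no variance trend, 4 and 1 with robust empirical Bayes, and 11 and 15 with array weights. An adjusted p of 0.01 and a minimum fold of 2 each left 1 and 0. Leaving out 1 library gave 1 to 3 rows higher in pectoral and 0 to 2 in tail libraries, or 0 to 3 and 0 to 2 with the filter repeated on the other 5. Without pectoral replicate 1 and tail replicate 4 together there were 0 and 0, with 2 libraries per group, and with the deposited p-values adjusted over all rows of the deposit 0 and 0 (219 unadjusted). Rows summed by gene name gave 2 and 1, and by Trinity gene 3 and 1. The cause was not tested, except that fewer libraries or rows entered some fits. TRINITY_DN18143_c9_g1_i1 passed in all fits of limma that tested it and changed 1 planned choice, and not in the fit without 2 libraries (adjusted p = 0.39), where its log2 fold change was 6.48.

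Of the replicate numbers, 2 are shared between groups and nothing says that they pair samples. With the replicate block 1 row was higher in pectoral and 0 in tail libraries, at 1 residual degree of freedom. Pectoral replicate 3 and tail replicate 4 share their numbers with no other library. With the block, the group difference therefore came from replicates 1 and 2 only. The block ended the calls adjusted over the list alone of NGFR, HOXB3, HOXB7, FOXP2 and ID4, and turned the rank of the progenitor list downward. The deviations of same-numbered libraries correlated at -0.03 and -0.00 across rows.

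The ribosomal protein list passed at a pseudocount of 0.1 (median -0.62, adjusted p = 0.016) or 0.5 (-0.60, adjusted p = 0.045), and with no filter (-0.58, adjusted p = 5.314e-04). At the reported settings its adjusted p was 0.82 with an estimated correlation. Without 1 library its median ranged from -0.79 to -0.33, and it passed without pectoral replicate 2 or 3 or tail replicate 2. Its adjusted p over all settings was highest with the estimated correlation. The other 10 lists stayed on their side of the threshold. Of 225 list values, 17 changed direction, and of 2937 values of single rows, 224 did, all without a call.

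The group difference in log2 units moved with the pseudocount for ISL1 (1.56 as reported, 3.67 at 0.1, 2.18 at 0.5, 0.54 at 5), ISL2 (3.13 at 0.1, 0.35 at 5) and SLC18A3 (1.59 at 0.1). The 9 calls adjusted over the list alone kept their direction in all 167 fits and lost the call in 59. These fits reuse the libraries in which the 9 were called, so the kept direction is no independent support. That adjustment was made within each list and not over the lists. Depth is unknown and limits low rows by an amount that cannot be stated.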

Other observations

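The tests on other splits of the libraries and on low values in pectoral replicate 1, and the sums over Trinity genes were chosen after the results were seen. The likeness of contigs within a component was noticed among the rows with the largest folds before it was tested over all components.

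Of 936 tested rows with a description, 16 had separated groups and an unadjusted limma p under 0.01. The number that chance would give was not worked out. The 11 of these rows outside the lists were picked after their values were seen. Alpha tubulins, the subunits of microtubules, were the most abundant of them. Tubulin alpha 2 stood at 238, 260 and 344 TPM in pectoral and 142, 51.0 and 9.52 TPM in tail libraries (log2 fold change 2.70, SE 0.72, limma adjusted p = 0.29). Tubulin alpha 8 like 2 stood at 139, 182 and 207 TPM against 56.4, 23.8 and 16.1 TPM (log2 fold change 2.59, SE 0.68, limma adjusted p = 0.29). Meis homeobox 1 b, a partner of Hox proteins, stood at 10.5, 4.33 and 24.98 TPM in pectoral and 0.417, 0.633 and 0 TPM in tail libraries. The Wnt receptor frizzled 7a stood at 3.94, 12.3 and 7.78 TPM against 0.732, 0 and 0 TPM. In the other direction, the row described as Cbp/p300-interacting transactivator, with Glu/Asp-rich carboxy-terminal domain, 4b stood at 3.35, 2.08 and 0 TPM in pectoral and 54.1, 28.9 and 26.8 TPM in tail libraries. H2A histone family, member X, a histone variant that marks DNA damage when phosphorylated, stood at 3.90, 13.3 and 4.36 TPM against 28.7, 27.5 and 71.6 TPM. At the reported settings 0 of the 11 passed over all rows tested by limma. Tubulin alpha 2 passed with robust empirical Bayes and array weights (limma adjusted p = 0.014 and 0.029), and tubulin alpha 8 like 2 with these and with quantile scaling (0.014, 0.025 and 0.047). The transactivator passed with array weights (limma adjusted p = 0.025), as did zgc:158803 and integral membrane protein 2Cb (0.043 each).

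In the authors' deposited table the first 4 rows, FOXP2, HOXB7, HOXA5 and ALDH1A2, stood ahead of the row with the smallest p, and their deposited p-values were 0.016, 0.0069, 0.50 and 0.37. By that table's p-values the highest ranked described row was heat shock protein 12B (9.484e-05), at 2.66, 2.14 and 2.51 TPM in pectoral and 0, 0.0165 and 0 TPM in tail libraries. Of the 10 highest ranked described rows 5 were higher in pectoral, TAC1 (4.014e-04) and MCM7 (0.00103) among them, and 5 in tail libraries. Of the latter, RAN binding protein 1 (8.265e-04) stood at 1.38, 1.58 and 1.14 TPM in pectoral and 4.98, 3.96 and 4.202 TPM in tail libraries, and taxilin alpha (0.00147) at 2.01, 2.14 and 0.678 TPM against 6.07, 5.31 and 5.56 TPM. After adjustment over the deposited table the smallest p was 0.50.

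With the 3 rows past the threshold, the number of splits of the 6 libraries was too small to give a share under 0.05. The real split gave 3 rows, the highest of the other 9 splits gave 1, and 1 of the 10 splits gave as many as the real one. One of the other splits, pectoral replicate 1 with tail replicates 1 and 2 against the rest, had more rows with an unadjusted p under 0.05 (316 against 264) and more separated rows (502 against 442) than the real one.

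Pectoral replicate 1 was above 0 in all but 5 of the 7080 rows, and a candidate explanation is that rows were chosen, or contigs assembled, by their level in this library. Of its rows above 0, 3.11% lay below 0.5 TPM, against at least 18.6% in each of the other 5 libraries. Its deposited rows summed to 50000 TPM, and those of the other 5 libraries to 48449 to 74224 TPM. Greater sequencing depth alone would have added low values to this library, not removed them, and the 18.6% argues against depth as the only cause. Choice of rows and assembly from these reads were not separated, and no biological explanation was tested. If the candidate holds, genes expressed only in the tail could not appear, and whether the choice also raised pectoral means stays open, since the percent of tested rows with a positive fold fell by 1.23 points, from 43.5% to 42.3%, without this library.

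Contigs of 1 Trinity component, a cluster of contigs that share sequence, had more similar fold changes than pairs of contigs matched on mean level. Over 947 pairs in 337 components the mean absolute difference of log2 fold changes was 1.06, against 1.404 in shuffled pairs, and the mean correlation of library deviations from the group means was 0.219, against 0.101. Both had a permutation p of 0.001, the smallest that 1000 shuffles can give. This is consistent with such contigs drawing on the same transcripts or reads, and co-expression of related genes was not tested.

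The component of FOXP2 also holds the FOXP1 row, whose Trinity gene has 4 rows, 3 of them without a description. Which proteins these 3 encode is not known here. The 1 that was tested, picked after its values were seen, stood at 13.5, 25.1 and 17.1 TPM in pectoral libraries. In tail libraries it stood at 0.181, 5.10 and 0 TPM (log2 fold change 3.30, SE 0.996, limma adjusted p = 0.40). Summed, the 4 rows gave 18.3, 37.1 and 21.5 TPM in pectoral and 0.181, 5.95 and 0 TPM in tail libraries (log2 fold change 3.66, SE 0.996, limma adjusted p = 0.23). The Trinity gene of NGFR has 3 rows, 1 of them described as cugbp, Elav-like family member 5a, and summed they gave 7.91, 14.6 and 13.96 TPM in pectoral and 0.314, 0.763 and 1.82 TPM in tail libraries (log2 fold change 2.77, SE 0.996, limma adjusted p = 0.60). Its component also holds TRINITY_DN18143_c9_g1_i1, and these values do not say which protein that contig encodes.

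Tail replicate 4 stood apart in some mitochondrially encoded genes, named after their values were seen. MT-CYB stood at 31.8 TPM there against 847 to 2642 TPM in the other 5 libraries, and MT-ATP6 at 9.58 TPM against 189 to 694 TPM. MT-ND4 stood at 949 TPM against 478 to 609 TPM, and MT-CO2 at 1051 TPM against 418 to 593 TPM.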
